A study of Caenorhabditis elegans with 2 samples.

How the data were processed

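ChIP-seq was performed on whole young adult Caenorhabditis elegans at 64 hours, in 2 biological replicates of 1 group, per the labels. The strain carries GFP inserted at the lin-26 locus with unc-119 as a rescue marker, and the fusion protein was precipitated with an antibody against GFP, per the labels. The antibody field of the labels names lin-26, and the description names GFP. Chromatin was sonicated to a size range of 200 to 800 bp, per the labels. Reads, alignments and signal tracks were not used here.

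The starting point was 8 deposited peak lists on assembly ce11, per the text deposited with the samples. There were 4 lists of all peaks ranked by the irreproducible discovery rate (IDR) and 4 lists passing a threshold on it. Each replicate had 1 ranked and 1 thresholded list made from its own alignments. The others, including a list called conservative, were made from the alignments of both replicates. All lists were made against a control alignment, per the same text. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. The deposited signal value is the peak caller's signal relative to the control, and it is not scaled between lists. The deposited score is a whole-number IDR score, and its lowest value in each thresholded list, 830, corresponds to an IDR of 0.01. The deposited −log10 of the global IDR in the ranked lists served to recount peaks at other thresholds. The ranked lists of the whole series also hold 4 columns with signal values of the inputs that IDR compared, which carry no sample name and were not used here.

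The less strict thresholded list of the whole series was taken as the main list. Peaks on the 6 nuclear chromosomes were analysed, and mitochondrial peaks were counted apart. Peak positions were compared with the WBcel235 genome sequence, the assembly that ce11 names, and with the Ensembl release 115 annotation. Gene symbols came from RefSeq through WormBase identifiers, which covered 99.98% of the genes. Coordinates are counted from 1.

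A promoter window ran from 1000 bp upstream to 200 bp downstream of each of 29314 annotated 5' ends of protein-coding genes. Shares of summits in promoter windows, on chromosomes and within 500 bp of 10 classes of non-coding genes were compared with shares of the genome by two-sided exact binomial tests. Intervals on shares are 95% Wilson intervals and cover counting error only. Neighbouring summits are not independent, so the lists were also shifted along each chromosome at 100 random offsets, and a share was called against them only beyond their range. Genes with a promoter summit in 23 gene lists were compared with all other protein-coding genes by two-sided Fisher exact tests. Matches to 20 consensus motifs in 150 bp windows at summits were compared with same-width windows 400 bp to each side by two-sided Fisher exact tests. Sequences of 6 bases were ranked on chromosomes I to III, and the first 20 were tested on IV, V and X. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Replicate peaks were called shared when they overlapped by at least 50% of the shorter peak. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0.

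The gene lists, the motifs, the tests, the main list and most alternatives were fixed before the data were examined. The rule for named genes was fixed then too. It covered lin-26, lir-1, lir-2, lir-3 and unc-119, the protein-coding genes whose promoter windows hold any of the 20 strongest peaks, and up to 4 members per gene list with the strongest promoter peaks. Of the 56 genes named by the last parts of this rule, the report names those that the comparisons rest on.

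Alternatives covered the conservative list, each replicate's own list, the stronger peaks only, other IDR thresholds, overlap rules, promoter windows, 5' ends, gene assignment, matched background genes, motif windows and backgrounds, sequence lengths and distances to non-coding genes. The alternatives that left out summits near tRNA, snoRNA and snRNA genes, kept only signal values of at least 30, left out the linker histone gene his-24, compared 6-base sequences with shuffled windows, used an IDR of 0.05 or shifted summits for non-coding classes were chosen after seeing the data. So was the removal of tRNA summits from the chromosome counts.

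The tests were first tested on simulated data. With 3000 evenly placed summits, the promoter test made 0 calls in 20 simulations. With summits added to promoter windows to a fold of 1.28, it recovered a mean fold of 1.28 and called it in 20 of 20. A tRNA fold of 9.71 was recovered as 9.67 with 3000 summits. Evenly placed summits gave 3 calls of non-coding classes and 1 call of a chromosome over 20 simulations. With 19973 genes and a share of 35% set for ribosomal protein genes, the mean share was 36.0%, called in 20 of 20. Random bound genes gave 0 list calls in the same number of simulations. Simulated summits and bound genes were drawn independently, so clustered summits and neighbouring genes that share a summit were not tested. A motif written into 10% of 1000 windows was called in 20 of 20, and unaltered windows gave 1 motif call over 20 simulations.

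The lists hold no read counts, so the depth of each replicate is unknown and no interval for signal values can be given. With 2 replicates and no second group, no between-group test was made.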

Results

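LIN-26 is a zinc-finger protein known for its role in epidermal fate in C. elegans. Its GFP fusion was mapped by ChIP-seq in whole young adults at 64 hours, in 2 biological replicates of 1 group. The data were lists of peaks, each with a position, a summit and a signal value relative to a control. The list built from both replicates held 3201 peaks, of which 3187 lay on the nuclear chromosomes and 14 on the mitochondrial genome. The nuclear peaks formed 2968 separate regions, had a median width of 336 bp and covered 0.964% of the nuclear genome. Their median signal value was 112.1. The conservative list held 2655 peaks. Read depth is unknown, because the lists carry no counts.

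The replicates shared most of the peaks of the shorter list and differed in number. Replicate 1 alone gave 1193 peaks and replicate 2 alone gave 2098, a ratio of 1.76. The ranked lists before thresholding held 55942 and 75491 peaks, a ratio of 1.35. Of the 1191 nuclear peaks of replicate 1, 79.0% (95% Wilson interval 76.6 to 81.2) overlapped a peak of replicate 2. Randomly shifted peaks overlapped in 0.650% on average and in at most 1.26% of cases. From the other side, 45.5% of the 2083 nuclear peaks of replicate 2 overlapped a peak of replicate 1. Signal values of 34568 matched ranked peaks had a Spearman correlation of 0.432 between replicates. The correlation was 0.808 across the 941 replicate 1 peaks past the threshold that overlapped a replicate 2 peak past it. Both correlations are across peaks, which are not independent replicates. Of the 3187 nuclear peaks in the list of both replicates, 930 overlapped a peak in each replicate's own list, and 1196 overlapped none in either.

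Genes for tRNAs, snoRNAs and snRNAs carried the strongest concentration of summits. These short RNAs serve translation, the modification of ribosomal RNA and splicing. The comparison asked whether peaks lie at such genes more often than their share of the genome. Within 500 bp of a tRNA gene lay 453 summits, or 14.2% of all, against 0.571% of the genome, a fold of 24.9 (22.9 to 27.1). These summits reached 502 of the 612 tRNA genes, or 82.0%. The highest share among 100 shifted lists was 0.973%. The fold was 14.2 (11.1 to 18.2) at snRNA genes, where 56 of 129 genes had a summit. It was 11.1 (9.42 to 13.1) at snoRNA genes, where 123 of 346 had one. The adjusted p-values were 2.0e-47 and 3.1e-89. Together, 643 summits (20.2%) lay near these 3 classes, which with their margins take up 1.08% of the genome. Replicate 1 alone gave folds of 54.7 at tRNA, 22.4 at snRNA and 19.03 at snoRNA genes, and replicate 2 alone gave 36.8, 18.8 and 14.2. The lists differ in length, and the 1191 strongest nuclear peaks of replicate 2, as many as replicate 1 has, gave 57.4, 22.4 and 17.9.

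**Figure D1:**
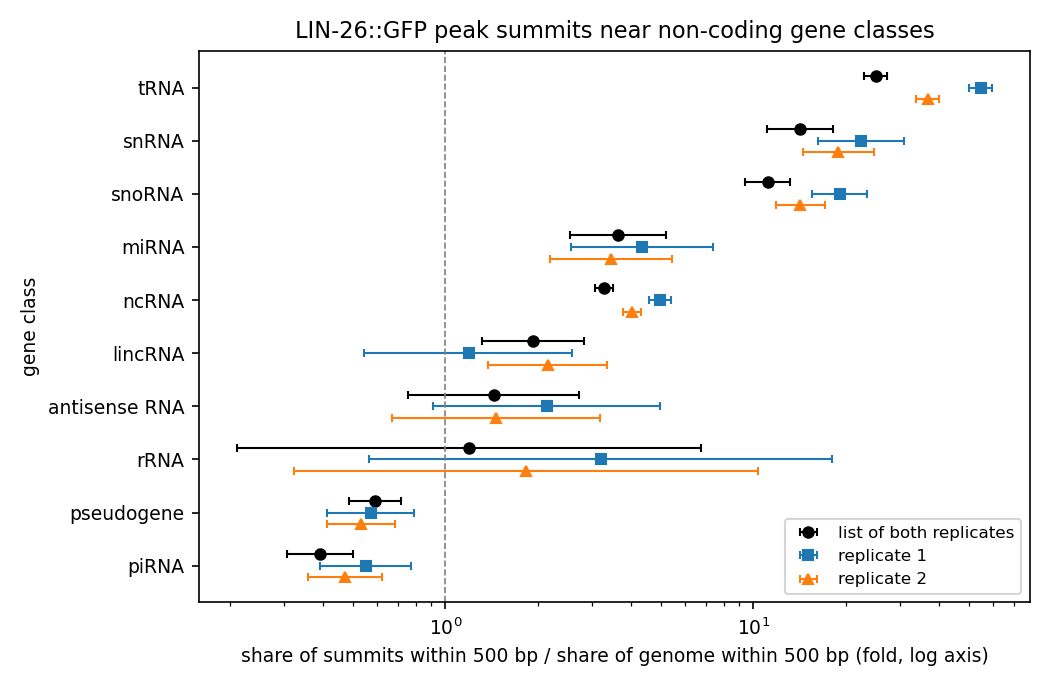
Each point gives the share of summits within 500 bp of a gene class divided by the share of the genome there, on a log axis, with 95% Wilson intervals for the list of both replicates and each replicate's own list. The tRNA class had the highest fold in each list, 24.9 in the list of both replicates.

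Summits gathered more tightly around the 5' end at tRNA genes than at snoRNA and snRNA genes. At tRNA genes the median summit lay 20 bp downstream of the gene's 5' end, in genes with a median length of 72 bp. Of the tRNA genes with a summit, 88.6% had it within 100 bp of the 5' end, against 59.3% of the snoRNA genes and 51.8% of the snRNA genes with one. The median lay at −13 bp at snoRNA genes, just upstream of the 5' end, and 82 bp downstream of it at snRNA genes. These genes are longer, with median lengths of 130 bp for snoRNA and 109 bp for snRNA genes. The difference between the classes was not tested. The gene for the RNA of RNase P, rpr-1, held a summit of signal 761, and mrpr-1, for the RNA of RNase MRP, held one of signal 341. Both names were chosen after their values were seen. Genes for miRNAs had a fold of 3.63, the class annotated as ncRNA 3.28 and lincRNA genes 1.93. The ncRNA fold was 1.85 (316 of 2544 summits) without the summits near tRNA, snoRNA and snRNA genes, and 4.98 in replicate 1 alone. The lincRNA call was lost in replicate 1 alone (fold 1.19, adjusted p 0.65) and in the stronger peaks alone (fold 1.78, adjusted p 0.064). The lincRNA share of 0.816% equalled the highest among 100 shifted lists, whose mean was 0.429%. Summits were less frequent than the genome share near piRNA genes (fold 0.393) and pseudogenes (fold 0.592). The rRNA and antisense RNA classes were not called, with 1 and 9 summits, but antisense RNA genes passed the threshold within 1000 bp (fold 1.82, adjusted p 0.022). Reads from near-identical copies of these genes cannot be assigned with certainty, and how the aligner treated them is not given in the sources used here. The class counts also leave out 81 nuclear ranked peaks that reached the lowest listed score but are absent from the thresholded list. Whether any of the 81 lie at rRNA genes was not tested, so the missing rRNA call does not show absent signal there.

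**Figure D2:**
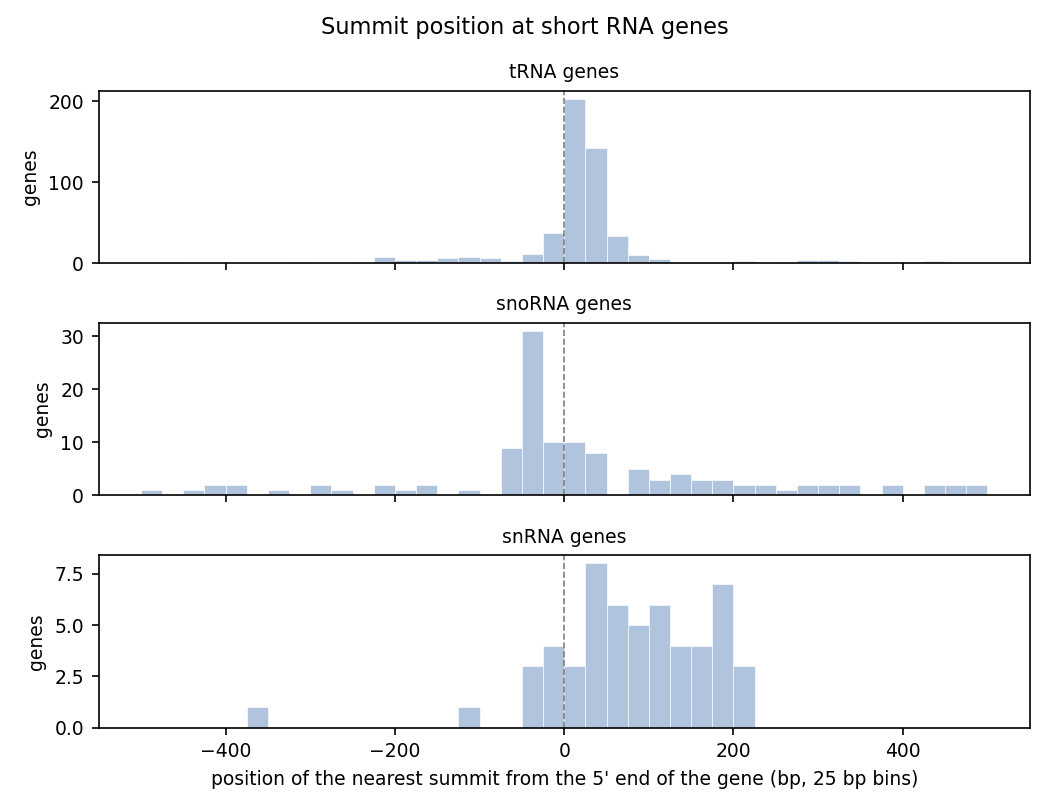
Bars count genes by the position of their nearest summit relative to the gene's 5' end, in bp, for tRNA, snoRNA and snRNA genes. Summits at tRNA genes gathered just inside the gene, with a median of 20 bp.

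Short RNA genes dominated among the strongest peaks. Of the 100 nuclear peaks with the highest signal, 63 had a summit near a tRNA, snoRNA or snRNA gene. The share was 69.0% among ranks 101 to 300, and 162 of 300 summits at ranks 301 to 600 lay near them. It was 25.3% among ranks 601 to 1200, 8.75% among ranks 1201 to 2000 and 4.89% below those. Peaks near these genes had a median signal of 214, and the other peaks 105. These ranks were divided after the values were seen, and signal values rank peaks within a list only. The 3 strongest nuclear peaks had no annotated tRNA, snoRNA or snRNA gene within 500 bp. They lay at II:12778417-12778797 in an intron of Y46G5A.34 (signal 3137), at I:5639193-5639606 outside genes (2778) and at IV:13430206-13430563 outside genes (2397).

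**Figure D3:**
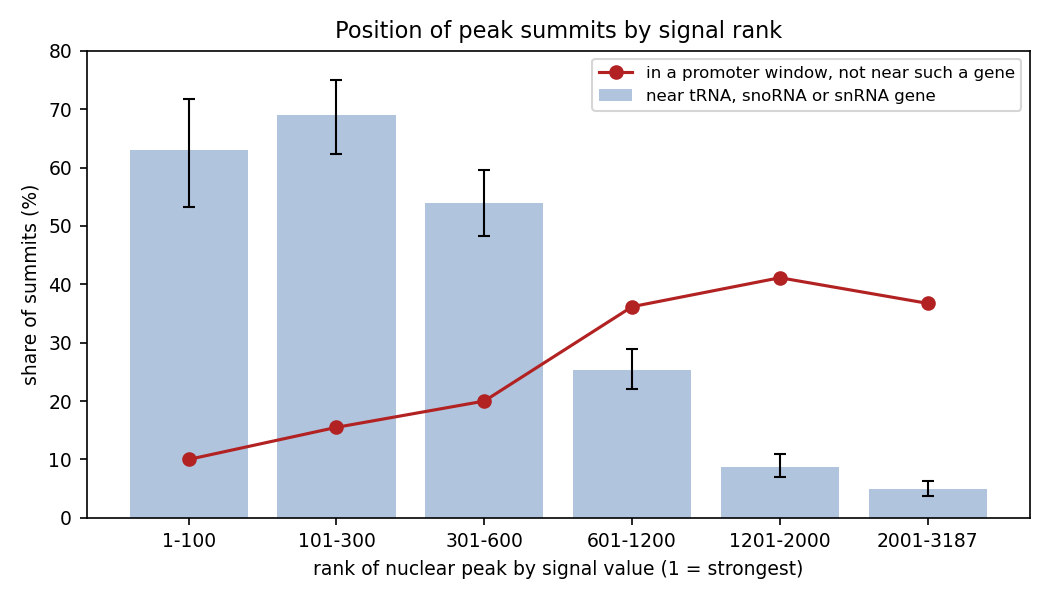
Bars give the share of summits (%) near a tRNA, snoRNA or snRNA gene by signal rank, with 95% Wilson intervals, and the line gives the share in a promoter window and away from such genes. The bars fell from 63.0% among the 100 strongest peaks to 4.89% among ranks 2001 to 3187, and the line ended at 36.7%.

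Summits were more frequent than the genome share in windows upstream of protein-coding genes. The comparison asked where along genes the fusion protein was found. Promoter windows held 1267 of 3187 summits, or 39.8% (38.1 to 41.5), against 26.1% of the genome. The fold was 1.52 (1.46 to 1.59, two-sided exact binomial p 6.8e-63), and shifted lists reached at most 27.9%. Replicate 1 alone gave a fold of 1.44 and replicate 2 alone 1.54. Protein-coding 3' UTRs had a fold of 2.19 and 5' UTRs 1.70, while coding sequence had 0.731 and introns 0.804. Coding sequence had 0.453 in replicate 1 alone and 0.507 in replicate 2 alone. The 5' UTR difference did not pass the threshold in replicate 1 alone (fold 1.33, p 0.12). This split by gene part was chosen after the main values were seen.

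Genes for ribosomal proteins, histones, developmental timing and chaperones carried promoter summits more often than other genes, and no list of tissue genes was called higher. The comparison asked which gene families and tissues carry LIN-26::GFP peaks. In all, 1329 of 19973 protein-coding genes (6.65%) had a promoter summit. Of 23 gene lists, 4 had a higher share than other genes and 1 a lower share, and 18 were not called. Ribosomal protein genes had a summit in 28 of 84 cases (33.3%, fold 5.10, adjusted p 3.9e-12), and the fold was 7.93 in replicate 1 and 6.20 in replicate 2. The strongest stood at rpl-3 (signal 729), rpl-35 (381), rpl-15 (362) and rps-24 (355), all present in both replicates' own lists. Of the 28 genes, 8 had their strongest peak in both replicates' own lists and 25 in at least 1. Histone genes, taken by their his- names, had a summit in 23 of 72 cases (31.9%, fold 4.87, adjusted p 9.0e-10). These include his-24, which encodes a linker histone, and without it 22 of 71 core histone genes had a summit (fold 4.72, adjusted p 4.4e-09). This removal was chosen after the values were seen. The strongest stood at his-59 (331), his-66 (311), his-61 (291) and his-58 (290). Their summits lay at −473, −775, −552 and −758 bp from the 5' ends. Those at his-59 and his-61 lay in coding sequence and that at his-58 in an intron. The histone fold was 9.85 in replicate 1 and 6.27 in replicate 2. It fell to 2.34 (adjusted p 0.17) with a window of 500 bp upstream to 100 bp downstream. Histone genes lie in clusters, are near-identical in sequence and can share a summit, so their number of independent sites is lower.

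Regulators of developmental timing and molting had a summit in 6 of 16 genes (37.5%, fold 5.66, adjusted p 0.0022). This list includes the membrane-bound transcription factor genes myrf-1 (signal 187) and myrf-2 (130), the heterochronic gene lin-46 (145) and the nuclear receptor gene nhr-85 (113). Of these 4 peaks, only that of myrf-1 was in both replicates' own lists, and the others were in replicate 2. Across all 6 genes with a summit, 4 had their strongest peak in at least 1 replicate's own list. The call was lost in replicate 1 alone (fold 2.53, adjusted p 1.0) and with only the outermost 5' end of each gene (fold 3.20, adjusted p 0.24). Heat shock and chaperone genes had a summit in 5 of 18 cases (27.8%, fold 4.19, adjusted p 0.025). The fold was 9.05 in replicate 1 alone (4 of 18 genes, adjusted p 0.0049) and 4.94 in replicate 2 alone. Peaks stood at hsp-3 (267), hsp-60 (203), hsp-1 (145) and hsp-6 (134). That call was lost in the conservative list (fold 3.96, adjusted p 0.062), with the 500 bp window (3 of 18 genes, fold 4.002, adjusted p 0.17) and against genes matched on upstream distance (3.74). Chemoreceptor genes, a large family of neuronal receptors, had a summit in 15 of 1301 cases (1.15%, fold 0.164, adjusted p 1.9e-21). The strongest of these, at sre-23 (signal 602), lay 60 bp from a snoRNA gene.

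**Figure D4:**
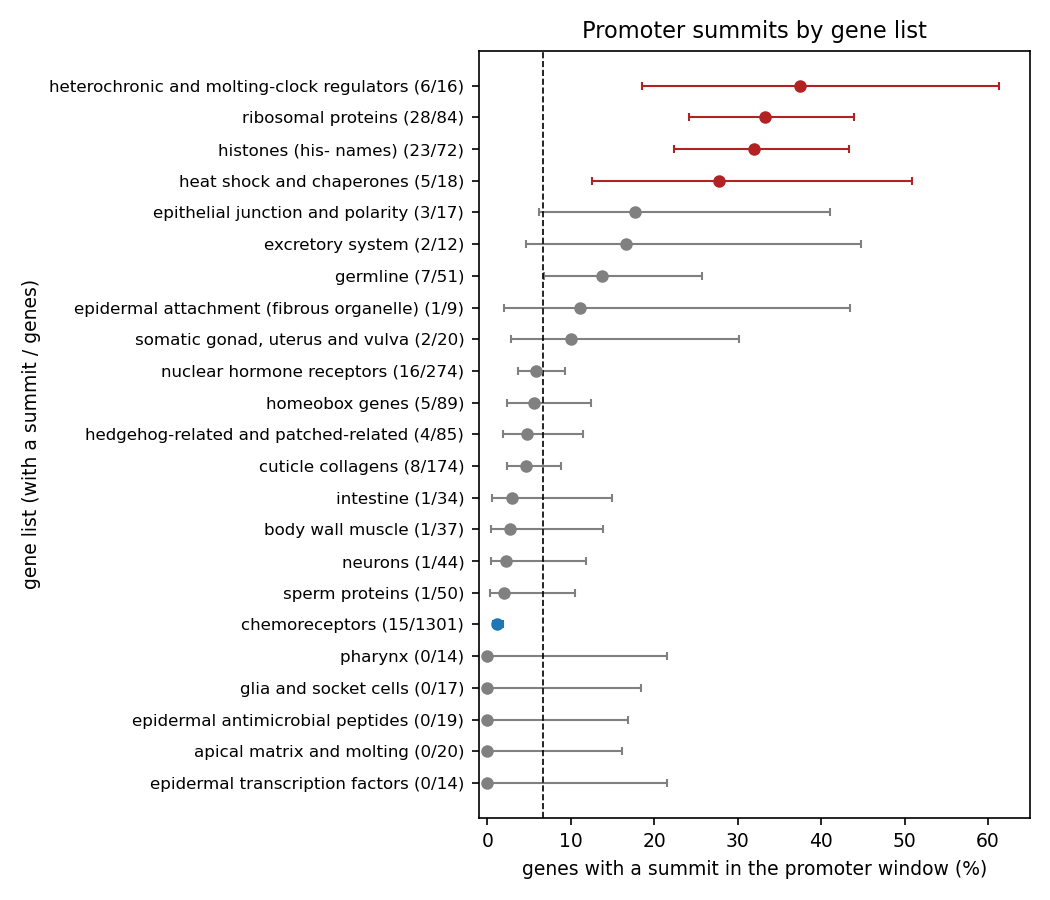
Each point gives the share of a list's genes (%) with a summit in the promoter window, with its 95% Wilson interval. The dashed line is the share among all protein-coding genes, 6.65%, red lists were higher, the blue list lower, and grey lists were not called.

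No list of epidermal genes was called with the peaks of both replicates. The lists of epidermal transcription factors (0 of 14 genes), apical matrix and molting genes (0 of 20) and epidermal antimicrobial peptides (0 of 19) had none. Cuticle collagen genes had one in 8 of 174 cases (fold 0.689, adjusted p 0.74). With each summit given to the nearest 5' end within 5000 bp, collagens reversed to a fold of 1.82 (adjusted p 0.0017). The strongest collagen peaks stood at col-185 (271), at a tRNA gene, and col-42 (271). Hedgehog-related and patched-related genes had a summit in 4 of 85 cases, led by wrt-3 (463). At 2 of these 4 genes the strongest peak lay near a short RNA gene, and without such summits 2 of 85 genes had one (fold 0.409, adjusted p 0.52). Genes of epithelial junctions and polarity had one in 3 of 17 (fold 2.66, adjusted p 0.33), at ajm-1 (303), spc-1 (190) and pkc-3 (154). The junction list passed the threshold in replicate 1 alone (fold 7.17, adjusted p 0.036) but not in replicate 2 alone (3.92) or the conservative list (4.19, adjusted p 0.061), and the ajm-1 peak lay at a tRNA gene. Epidermal attachment genes had a summit in 1 of 9. The short lists limit what could be detected, as the interval for 0 of 14 genes reached 21.5%.

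Lists of other tissues were not called either. Glia (0 of 17) and pharynx (0 of 14) had no promoter summit, and the excretory system (2 of 12), gonad (2 of 20), intestine (1 of 34), muscle (1 of 37), neurons (1 of 44) and sperm (1 of 50) had few. Germline genes had one in 7 of 51 cases (fold 2.07, adjusted p 0.31), with 0 of 51 in replicate 1 alone and 3 of 51 (fold 1.30) in replicate 2 alone. None of the 7 genes had its strongest peak in both replicates' own lists. The list passed the threshold when summits were given to the nearest 5' end (fold 2.75, adjusted p 0.00069). Nuclear hormone receptor genes had one in 16 of 274 and homeobox genes in 5 of 89.

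Among lin-26, 3 genes with related names and unc-119, only lir-1 held a thresholded peak. The gene lin-26 (II:7682198-7684764) had no thresholded peak within the gene or 1000 bp around it, and its best ranked peak, at II:7683921-7684256, had an IDR of 0.099. Its neighbour lir-1 held 1 peak, at II:7677490-7677825 in an intron, with signal 103.8. That peak was in neither replicate's own list nor the conservative list. The genes lir-2, lir-3 and unc-119 had no thresholded peak, and the best ranked peak at unc-119, the marker of the inserted construct, had an IDR of 0.069. The protein-coding genes with promoter windows at the 20 strongest peaks were F59C6.18 (I:10516870-10517339, signal 1063, at a snoRNA gene), T01A4.9 (I:4466909-4467208, 935), and K01G5.10 and tasp-1, which share a peak (III:10759121-10759370, 751).

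Summits were unevenly spread over the chromosomes. Relative to length, chromosome III had a fold of 1.31 (adjusted p 3.6e-11) and chromosome V 0.756 (adjusted p 2.1e-12). Chromosome I had 1.13 (adjusted p 0.0059) and IV 0.915 (adjusted p 0.042), and neither call was kept in either replicate alone or the conservative list. The fold for I was 1.112 in replicate 1, 1.108 in replicate 2 and 1.083 in the conservative list, and for IV 0.977, 0.911 and 0.990. Chromosome X had 1.02 (adjusted p 0.77), but it carries 276 of the 612 tRNA genes. Without summits near tRNA genes the X fold was 0.751 (adjusted p 1.7e-09) and was called lower. With those summits kept, the X fold was 1.33 in replicate 1 alone (adjusted p 1.5e-06) and 1.15 in the stronger peaks alone (adjusted p 0.010). Relative to promoter windows, chromosome III had 1.36, I had 1.38 and V had 0.687. The central segment of the chromosomes, which spans 33.3% of the genome, held 36.1% of summits (fold 1.08, p 0.0011).

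Sequence at the summits carried tRNA promoter elements, GC-rich elements and repeats of GA, but not all at the same peaks. The comparison asked which known binding motifs lie under the peaks. Of 20 motifs, 10 were more frequent in summit windows than in flanking windows and 5 less frequent. Summit windows had 46.2% GC and flanks 36.9%, so the windows were also compared with their own dinucleotide-shuffled sequence. Against both backgrounds 8 motifs were higher and 0 lower. The tRNA B box, an internal promoter element, occurred in 6.37% of summit windows and 0.157% of flanks (fold 40.6, adjusted p 2.3e-78). The EOR-1-like motif GAGACGCAGA occurred in 3.48% against 0.471% (fold 7.40), and the GA repeat had a fold of 3.63. The summits were also split, after the values were seen, by nearness to tRNA, snoRNA and snRNA genes. The B box occurred in 179 of 643 windows near them and 24 of 2544 away from them. Near them the EOR-1-like motif (fold 0.686, adjusted p 0.82) and the GA repeat (1.83, adjusted p 0.28) were not called against flanks. The others higher against both were KLF/Sp (2.78), the E-boxes CACGTG (2.14) and CAGCTG (1.41), E2F (2.02) and PHA-4 (1.40). Near short RNA genes KLF/Sp (2.76) and E2F (1.86) were called against flanks, and CACGTG (0.610), CAGCTG (0.784) and PHA-4 (1.49) were not. The CAGCTG call was lost in replicate 1 alone (1.28, adjusted p 0.24) and in replicate 2 alone (1.09, adjusted p 0.58). Against shuffled sequence KLF/Sp fell to 1.23 and E2F to 1.32.

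The GATA motif, which binds epidermal and intestinal factors, was less frequent at summits than in flanks (fold 0.822, adjusted p 5.6e-07) but not against shuffled windows (1.07, adjusted p 0.23). The nuclear receptor site RGGTCA was higher than in flanks (1.56) and not than in shuffled windows (0.882). The Grainyhead motif was higher than in flanks (1.38, adjusted p 0.030) and not than in shuffled windows (1.02), and the call was lost in each replicate alone (1.39 and 1.34). The heat shock element was higher only against shuffled windows (13.7, adjusted p 7.2e-09). The homeodomain, trans-splice acceptor, T-run and SKN-1-like motifs were lower against flanks (0.399, 0.476, 0.430 and 0.647) and none was called lower against shuffled windows, where the T run was higher (1.35). With 6-base sequences ranked on chromosomes I to III, 20 of 20 passed on the other chromosomes against flanks. Against shuffled windows, a comparison chosen after the values were seen, 18 of the 20 passed, with folds of at most 3.06. The first, CGAACC, had a fold of 8.28 against flanks and 3.06 against shuffled windows, and its reverse complement GGTTCG is part of the B box.

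**Figure D5:**
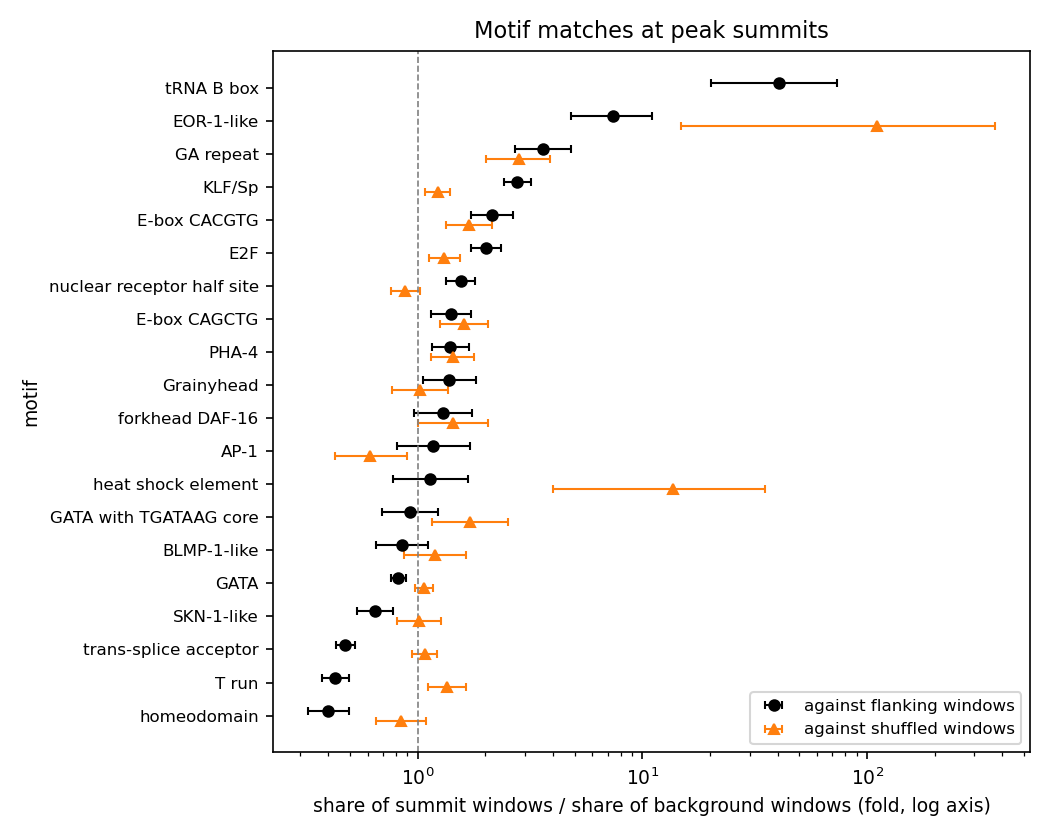
Each point gives the share of summit windows with a motif divided by the share of background windows, on a log axis, with 95% intervals, against flanking windows (circles) and dinucleotide-shuffled windows (triangles). The B box had a fold of 40.6 against flanks and no match in shuffled windows, and the GATA motif moved from 0.822 to 1.07.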

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

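The tests of strongly transcribed genes and of RNA polymerase III genes as the only ones with summits were chosen after the results were seen. So were those of tRNA-like sequence and of repeated sequence. Those of identical tRNA copies and of U6 genes were chosen before.

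Signals outside the main measurement were found on the mitochondrial genome and in the ranked list. The list of both replicates held 14 mitochondrial peaks on a genome that makes up 0.0138% of the sequence, and 6 of the 10 strongest peaks were among them. Replicate 1 alone had 2 such peaks, replicate 2 alone 15 and the conservative list 2. No explanation of the mitochondrial peaks was tested. In the ranked list, 81 peaks reached the lowest listed score and were not in the thresholded list. Their median signal was 146, against 112.1 for the listed peaks, and the strongest had a signal of 2190 at X:15810936-15811110. Of the 81, 6 lay near a tRNA, snoRNA or snRNA gene, and the reason for their absence is not given in the sources used here. The thresholded lists name 1 more parent file than the ranked lists, per the text deposited with the samples, which does not describe that file. Whether it removed these peaks was not tested.

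Summits gathered at tRNA, snoRNA and snRNA genes. The explanation by reads shared between identical copies predicted that single-copy tRNA genes would have summits at less than 0.5 of the multi-copy share. Of 140 tRNA genes whose sequence occurs once, 62.1% had a summit, against 87.9% of 472 genes with identical copies. The ratio of 0.707 (0.618 to 0.808) lay above the 0.5 set beforehand. How many tRNA summits come from shared reads cannot be told, as near-identical copies counted as single-copy. A neighbour's summit within 500 bp counted too. RNA polymerase III genes were not the only short RNA genes with summits. The 56 of 129 snRNA genes with a summit, seen before this test, already implied that, as only 22 are U6 genes. Of 106 snRNA genes other than U6, which RNA polymerase II transcribes, 45.3% had a summit, and shifted lists reached at most 8.49%. The gene mir-1831, annotated as snRNA but named as a miRNA, had summits and was left out of these counts, and with it, a count made after the results were seen, the share was 45.8% of 107. A preference for RNA polymerase III genes stays open. The share of the 22 U6 genes, 31.8%, was lower and so ran opposite to it, without passing the threshold (Fisher exact p 0.34). Against the 66 other snRNA genes left without SL and SmY RNA genes, 54.5% with a summit, p was 0.086. The share of tRNA genes, which RNA polymerase III transcribes, ran with the preference, as 82.0% had a summit against 45.3% of the 106 other snRNA genes. Which polymerase transcribes each snoRNA gene was not established here, so their share of 35.5% bears on neither side. These classes were not compared by a test. Whether strongly transcribed chromatin in general contributes stays open. Ribosomal protein genes kept a fold of 4.85 (3.41 to 6.91) after summits near short RNA genes were left out. That test could hardly fail, as only 5 of the 28 such genes with a summit had their strongest peak near a short RNA gene. No expression data were used here, so other strongly transcribed genes were not compared. Whether the summits at short RNA and ribosomal protein genes are binding of LIN-26 or signal that any precipitation gives at such sites was not tested.

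Among the 300 strongest nuclear peaks, 99 had no tRNA, snoRNA or snRNA gene within 500 bp. Unlisted tRNA-like sequence may account for some of them, as 7.07% had the relaxed B box GGTTCGANNCC, against 0 of 184 flanking windows. It cannot account for most, since that share was 0.108 (0.0526 to 0.224) of the one at equally strong summits near tRNA genes. Repeated sequence stays open, as 46.5% (36.96 to 56.2) of the 99 had another copy in the nuclear genome, and 30.3% of windows 1000 bp away did. A copy had at least 90% identity over at least 100 bp. The median tRNA gene is 72 bp long, so an identical copy of such a gene alone does not count, and the shares of peaks near and away from short RNA genes are not comparable. Among weaker peaks away from short RNA genes the share was 15.3% (14.6% of windows 1000 bp away), and among the other 201 of the 300, near short RNA genes, 31.8% (10.4%). No biological explanation was tested.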

How the results depend on the processing

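The alternatives with an IDR of 0.05, with signal values of at least 30, without summits near tRNA, snoRNA or snRNA genes (for chromosomes also without those near tRNA genes alone), with shifted summits for non-coding classes, without the linker histone gene his-24 and with shuffled windows for 6-base sequences were chosen after the results were seen. No paired analysis was possible because the series has 1 group.

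The promoter excess kept its direction and its call under each alternative run. Peak counts ranged from 1193 to 2098 without either replicate, and were 9910 at an IDR of 0.1 and 6719 at 0.05. Replicate overlap was 81.4% with an overlap of 1 bp and 70.4% with equal numbers of top peaks, and the signal correlation was 0.808 for peaks past the threshold. Chromosomes called higher, 2 in the main list, and lower, also 2, each fell to 1 in the conservative list. Without either replicate 1 to 2 were higher and 1 lower. The lower count was 1 in the stronger peaks and 1 with signal values of at least 30. Gene lists called higher fell from 4 to 2 with 500 bp upstream and 100 bp downstream, a window that holds fewer summits.

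The alternatives gave 777 values of single lists, motifs, gene classes, chromosomes and named peaks. Named peaks had no test and counted as kept when they overlapped a peak of the other list. Of the 777, 689 stayed on their side of the threshold with no change of direction in a called value, or kept the overlap. A further 72 lost the call or the overlap, and 6 gained a call. In 10 the fold crossed 1 with a call on at least 1 side, which need not be a call in both directions. For the gene lists alone, 268 of 277 stayed. As 18 of the 23 lists were not called in the main list, most of these values only had to stay uncalled. Motifs called lower fell from 5 to 1 against shuffled windows. There the fold crossed 1 for GATA (1.07), TGATAAG (1.72), RGGTCA (0.882), AP-1 (0.616), SKN-1-like (1.01), the T run (1.35) and the trans-splice acceptor (1.08). Only the T run was called in both directions. TGATAAG and AP-1 were called only against shuffled windows, and the others only against flanks. The X chromosome, not called in the main list, had a fold of 0.796 without summits near tRNA, snoRNA and snRNA genes. Its fold was 0.751 without those near tRNA genes. This removes the summits at its 276 tRNA genes. Cuticle collagens, also not called in the main list, had a fold of 1.82 with the nearest 5' end. The cause of the other changes was not tested. Without the summits near short RNA genes, tRNA, snoRNA and snRNA genes hold none by construction and get no value. Read depth, which is unknown, limits what the difference in peak number between replicates can show.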

Other observations

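The tests in this part were all chosen after the results were seen, and no explanation is offered for the values. Outside promoter windows, 184 summits lay in 3' UTRs, a fold of 2.26 (1.961 to 2.60, adjusted p 5.0e-23), while coding sequence had 0.583 and introns 0.726. Among the 2544 summits away from tRNA, snoRNA and snRNA genes, the EOR-1-like motif had a fold of 10.2 (lower bound 6.17), the GA repeat 3.90, KLF/Sp 2.79 and the B box 10.8, with 24 windows. Among snRNA genes, a summit lay near 11 of 18 SL2 RNA genes, 0 of 12 SL1 RNA genes and 1 of 10 SmY genes. These counts leave out the 81 ranked peaks absent from the thresholded list, of which 6 lay near a tRNA, snoRNA or snRNA gene. Whether those 6 lie at SL1 RNA genes was not tested, so the 0 of 12 does not show absent signal. Each of the 3 strongest nuclear peaks had other matches of at least 100 bp and 90% identity in the nuclear genome, with a best identity of 92.6% on chromosome II, 97.9% on I and 97.2% on IV. Those on II and IV matched each other at 90.6% identity over 287 bp.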
